A study of Homo sapiens with 6 samples.

How the data were processed

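RNA was sequenced from HT-1080 human fibrosarcoma cells treated for 48 h with DMSO, 2 µM palbociclib or 500 nM pimasertib, with 2 libraries per group. Per the labels' protocols, cells were scraped into buffered saline, RNA was purified on columns, cDNA was primed with random hexamers, and adaptor-ligated fragments were selected by size before sequencing. Whether reads were counted by strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be told apart. The submitters' processing notes name CASAVA, STAR 2.5, HTSeq 0.6.1 and DESeq2, and the builds hg19 and GRCh37, without the order or settings of the steps. The authors deposited 1 table per drug, each with raw read counts per gene for the drug's libraries and the DMSO libraries, FPKM values, which were not used here, and the results of their own comparison with DMSO. Per the file headers, the authors' log2 fold changes, p-values and adjusted p-values belong to that comparison, and they were used only to count the calls shared with the test below. The deposited log2 fold changes are smaller than plain log2 ratios of the group means, so they were set beside no fold change here.

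The tables held 23914 and 24931 genes, of which 22559 were in both and 26286 in either. The DMSO counts of shared genes were identical in both tables, and a gene absent from 1 table had no DMSO read, so its missing counts were set to 0. Libraries were named by the table columns that carry their labels, and no column was left without a sample. Totals ranged from 13607490 to 17500655 counts per library, with 98.3% to 98.7% of counts in protein-coding genes. Intervals of count ratios are exact 95% intervals and, like floors of 3 counts, cover counting error only, since PCR copies of a read are not independent molecules.

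The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr within groups (minimum count 10, minimum total 15), which left 14839 genes, 12566 of them protein-coding. Libraries were scaled by TMM, and 1 model of 3 groups over all 6 libraries was fitted with glmQLFit (robust), so that all groups shared the estimate of the spread. Each pair of groups was compared with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM values are counts divided by the TMM-scaled library total, on the usual CPM scale, and log2 CPM for display and for list tests used a prior count of 2.

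Gene lists were written from textbook knowledge of CDK4/6 and MEK inhibition, ferroptosis, stress pathways, other cell types and RNA quality. The 26 lists were DNA replication and G1/S, G2/M and mitosis, cell cycle brakes and cyclin D/RB, ERK/MAPK output, receptor tyrosine kinases and ligands, p53 targets, ferroptosis-protective and ferroptosis-promoting genes, NRF2 targets, ATF4/amino acid stress, cholesterol synthesis, fatty acid and phospholipid remodelling, interferon-stimulated genes, antigen presentation, senescence-associated secretory genes, lysosome, extracellular matrix, contractile and SRF/YAP targets, ribosome biogenesis and MYC targets, glycolysis, epithelial, leukocyte and endothelial markers, mitochondrially encoded genes, cytosolic ribosomal proteins, and RNA stress genes. The last of these lists holds RNA stress and dissociation-response genes and is called RNA stress for short. Some genes sit in more than 1 list, such as CCND1, HMOX1, MBOAT1, SLC7A11 and ATF3. Each list was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over 78 tests of 26 lists in 3 comparisons. Of these, 36 passed, and none did with an estimated correlation, which with so few libraries is itself imprecise. That variant also rests on the few residual degrees of freedom of the libraries, so a list could hardly pass. For interferon-stimulated genes in palbociclib the estimated correlation was 0.0100, near the preset. The unadjusted camera p still went from 5.59e-06 to 0.0200. A list that does not pass with an estimated correlation thus does not show that correlation between its genes explains the result.

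The tests, the thresholds, the lists and the rule for named genes were fixed before the data were examined. That rule is as follows. For each drug against DMSO these are the 8 raised and 8 lowered protein-coding genes with the largest log2 fold change among those past the threshold, with a mean normalized count of at least 100 and both treated libraries beyond both DMSO libraries, and for the drugs against each other 6 each way. Up to 4 members of each list past the threshold are named per direction, and some genes that the rule takes are not reported here. CDK4, CDK6, RB1, CCND1, CCNE1, CCNE2, CDKN1A, MAP2K1, MAP2K2, DUSP6, GPX4, ACSL4, SLC7A11, AIFM2, MBOAT1, MBOAT2, EMP2 and TFRC are named whatever their value. GPX4, MBOAT1, MBOAT2 and EMP2 were in that set because the submitting laboratory is known to study ferroptosis, so their directions are not independent evidence if the study chose them on these samples. A fold against a group without counts is given as a lower bound against 3 counts over the group, and with 1 to 3 counts as a count ratio with its interval.

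Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter and a stricter filter (mean normalized count of at least 50) on low counts, the replicate number as a block, the 4 libraries of a comparison alone, a size threshold of 1 on the log2 scale, protein-coding genes alone, fry and an estimated correlation for lists, and leaving out each library in turn. In fits on fewer libraries the genes were those of the full fit, except that 14830 were tested from the 4 libraries of palbociclib and DMSO. The 4 libraries of a comparison with the replicate block were added after the data were seen. The scripts were tested on simulated counts with 200 genes changed per drug. The edgeR test recovered 73.4% of 4-fold, 16.4% of 2-fold and 2.99% of 1.5-fold changes for palbociclib, and 87.1%, 21.2% and 1.49% for pimasertib, over 14450 simulated genes that passed the filter. False calls were 7 of 67 for palbociclib and 6 of 75 for pimasertib with edgeR, more than the nominal share, 21 of 95 and 21 of 100 with the DESeq2 Wald test, and 4 of 62 and 7 of 76 with limma-voom.

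The overlap of the drugs was set beside 50 simulations of unchanged groups. In these, all 6 libraries were drawn from the DMSO means, independently for each gene, and both drug groups shared the simulated DMSO libraries. For checks of gene properties, GENCODE 29 transcripts (GRCh38) gave GC content for 14417 genes and translated sequences for 12368, and no coordinates were taken from that build. A hydrophobic segment was a stretch of 19 residues with a mean Kyte-Doolittle hydropathy of at least 1.6, or of 9 residues with at least 2 within the first 30. Groups of 2 are too small for splits of the samples or an outlier test. Genes with near-identical copies or processed pseudogenes, such as HLA-B, HLA-C, ferritin, keratin and ribosomal protein genes, are uncertain, since the treatment of reads that match several genes is not given in the sources used here.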

Results

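RNA sequencing read counts per gene were measured in HT-1080 cells, a human fibrosarcoma cell line, after 48 h with 1 of 3 treatments. Cells received the vehicle DMSO, 2 µM palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6 that drive cells from G1 into S phase, or 500 nM pimasertib, an inhibitor of the kinases MEK1 and MEK2 that activate ERK. Each group had 2 libraries, 6 in all. Library totals were 16753274 and 15051223 counts in DMSO, 13607490 and 17500655 in palbociclib and 17007644 and 15673202 in pimasertib. A count of 3 corresponded to 0.168 to 0.220 CPM (library-scaled counts) in single libraries. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Levels below are mean ± SD of CPM with n = 2 per group, and fold changes are log2 with their SE and the adjusted p of the edgeR quasi-likelihood test. Where no library is named beside the call of a gene that the fixed rule names, the call held in all 6 fits that left out 1 library. Gene positions are on GRCh37, as the deposited tables give them, and span the whole gene.

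The pimasertib libraries stood apart from the other 4. In a principal component analysis of log2 CPM, the first component held 57.4% of the variance, with scores of 63.9 and 82.3 for pimasertib and −69.5 to −0.79 for the others. The second component held 18.4% of the variance and set DMSO (32.0 and 35.0) against palbociclib (−54.3 and −23.8). The third, with 13.0%, separated the replicate numbers, at −26.3, −14.0 and −31.3 for replicate 1 and 25.5, 41.1 and 5.09 for replicate 2 of DMSO, palbociclib and pimasertib. The replicate numbers differed on the first component too, where replicate 2 lay further towards the pimasertib side in each group. Its scores for replicates 1 and 2 were −69.5 and −32.5 in DMSO, −43.4 and −0.79 in palbociclib and 63.9 and 82.3 in pimasertib. The share of counts from the 13 mitochondrially encoded genes was 3.21% and 5.67% in DMSO, 4.57% and 6.31% in palbociclib and 4.25% and 8.76% in pimasertib, higher in replicate 2 of each group. Genes for proteins with a hydrophobic segment, the mark of most secreted and membrane proteins, were also higher in replicate 2. Their median log2 difference between replicates exceeded that of the other genes by 0.443 in DMSO, 0.262 in palbociclib and 0.342 in pimasertib, over 4835 genes with and 7533 genes without such a segment. Replicates of a group differed beyond sampling noise, with a chi-square of 57.8, 42.6 and 51.4 per degree of freedom. Separately prepared libraries of 1 culture may differ beyond it too, and by how much was not tested.

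The comparison of palbociclib with DMSO asked which genes changed when CDK4/6 was inhibited. Genes of DNA replication and mitosis fell together. MKI67, a marker of proliferating cells (ENSG00000148773, chromosome 10, positions 129894923 to 129924649, minus strand), was at 994 ± 252 CPM in DMSO and 168 ± 38.3 CPM in palbociclib, 5.92-fold lower, with a log2 fold change -2.56 (SE 0.28; adjusted p = 0.00163). CCNA2, which encodes cyclin A2 of S and G2 phase (ENSG00000145386, chromosome 4, positions 122737599 to 122745087, minus strand), was at 145 ± 15.5 and 27.3 ± 5.39 CPM, with a log2 fold change -2.41 (SE 0.25; adjusted p = 0.00161). E2F2 and E2F1, transcription factors of S-phase entry, had log2 fold changes of -3.75 (SE 0.42) and -1.72 (SE 0.24), with adjusted p of 0.00163 and 0.00319. A smaller set of genes rose, among them TXNIP, an inhibitor of thioredoxin and of glucose uptake (ENSG00000117289, chromosome 1, positions 145438469 to 145442635, plus strand), at 3.74 ± 1.6 CPM in DMSO and 22.2 ± 10.7 CPM in palbociclib, with a log2 fold change 2.58 (SE 0.38; adjusted p = 0.00446).

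Of 40 tested genes of DNA replication and G1/S (E2F targets), 34 fell, and 39 fell when adjusted over the list alone, with a median log2 fold change of -1.60. The set test camera gave an adjusted p of 3.48e-41 with its preset correlation, and 0.394 with an estimated correlation. Examples were RRM2, a subunit of ribonucleotide reductase (-2.16, adjusted p 0.00294), MCM10, a replication initiation factor (-2.36, adjusted p 0.00163), and ORC1 of the origin recognition complex (-2.29, adjusted p 0.00246). Of 36 G2/M and mitosis genes, 35 fell (36 adjusted over the list alone; median -1.66; camera adjusted p 6.90e-45, or adjusted p 0.328 with an estimated correlation). Among them, AURKB and PLK1, kinases of mitosis, changed by -2.16 (adjusted p 9.74e-04) and -1.75 (adjusted p 0.00174), and FOXM1, a transcription factor of mitotic genes, by -1.85 (adjusted p 0.00342). The replicate 2 libraries themselves were slightly lower than replicate 1 in these genes, with median log2 differences for the replication list of -0.34 in DMSO, -0.18 in palbociclib and -0.26 in pimasertib.

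The 8 genes with the largest decreases at 100 or more mean normalized counts were FAM111B (-3.60), WDR76, PIF1, SYNE2, MBOAT1 (-2.81), EMP2 (-2.79), SPC25 and ZNF367 (-2.58). MBOAT1, a lysophospholipid acyltransferase (ENSG00000172197, chromosome 6, positions 20100935 to 20212670, minus strand), went from 20.2 ± 2.39 to 2.84 ± 0.808 CPM, with a log2 fold change -2.81 (SE 0.30; adjusted p = 0.00163). EMP2, an epithelial membrane protein (ENSG00000213853, chromosome 16, positions 10622279 to 10674555, minus strand), went from 59 ± 5.37 to 8.55 ± 0.453 CPM, with a log2 fold change -2.79 (SE 0.22; adjusted p = 8.93e-04). The largest increases by the same rule were those of TXNIP, TSC22D3 (2.14), a glucocorticoid-induced leucine zipper protein, SESN3 (2.02), a sestrin, MXD4 (1.97), which binds MAX in competition with MYC, CNDP1, PIK3R3, C17orf103 (current symbol NATD1) and MYL9 (1.72), a regulatory light chain of myosin.

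Among 15 genes of cyclin D, RB and the cell cycle brakes, 3 fell (4 adjusted over the list alone). These were CDKN2C (-1.87, adjusted p 0.0019), which encodes the CDK4/6 inhibitor p18, RBL1 (-1.82, adjusted p 0.00246), which encodes the RB relative p107, and CDK2 (-1.22, adjusted p 0.0143, but 0.0525 without palbociclib replicate 1). The list test gave an adjusted p of 0.00892, or 0.663 as an adjusted p with an estimated correlation and 0.0578 without DMSO replicate 1. CCNE2, a cyclin of S-phase entry, fell by 1.74 on the log2 scale (adjusted p 0.0204), which did not pass without DMSO replicate 1 (adjusted p 0.0848), palbociclib replicate 1 (0.0525) or palbociclib replicate 2 (0.0819). The drug's targets CDK4 and CDK6 did not pass, at -0.31 (SE 0.23, adjusted p 0.541) and 0.21 (SE 0.30, adjusted p 0.766). The same held for RB1 (-0.24, adjusted p 0.65), CCNE1 (-0.22, adjusted p 0.732), CDKN1A (-0.33, adjusted p 0.475) and CCND1, which encodes cyclin D1 and was at 1185 ± 402 CPM in DMSO and 2018 ± 642 CPM in palbociclib (0.77, adjusted p 0.245).

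Interferon-stimulated genes lay higher as a list in palbociclib. Of 24 tested, 3 rose (10 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.63. With no filter on low counts, where members below the filter could also count, 7 rose and 1 fell, and with DESeq2 4 rose and 1 fell. The camera adjusted p was 3.11e-05, or an adjusted p of 0.312 with an estimated correlation. IFIT2, an antiviral effector, had a log2 fold change 2.15 (SE 0.31; adjusted p = 0.00392). The other 2 were SAMD9L (1.33, adjusted p 0.0174), which did not pass without palbociclib replicate 1 (0.0557) or pimasertib replicate 1 (0.051), and DDX58, the RNA sensor now named RIGI (0.91, adjusted p 0.0375), which did not pass without DMSO replicate 1 (0.207), either palbociclib library (0.0525 and 0.123) or either pimasertib library (0.08 and 0.077), or from the 4 libraries of the comparison (0.0713). Without pimasertib replicate 1 the count was 1 gene, and 1 fell without DMSO replicate 2 or palbociclib replicate 1. Among 17 contractile and SRF/YAP target genes, 2 rose (4 adjusted over the list alone). These were MYL9 and TGFBI (1.13, adjusted p 0.0276, but 0.142 without DMSO replicate 1, 0.0692 without pimasertib replicate 1, 0.0677 without pimasertib replicate 2 and 0.0618 from the 4 libraries of the comparison). The list's adjusted p was 0.0213 (adjusted p 0.655 with an estimated correlation), and 0.0646 without DMSO replicate 2.

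Ferroptosis is an iron-dependent cell death by lipid peroxidation. Of 24 ferroptosis-protective genes 1 fell in palbociclib by the edgeR test, MBOAT1 (2 adjusted over the list alone), which was also the gene that fell among 30 genes of fatty acid and phospholipid remodelling (of which 1 rose without DMSO replicate 2). As a set the protective list lay lower but did not pass (median -0.13, camera adjusted p 0.0749, or adjusted p 0.655 with an estimated correlation). GPX4, the glutathione peroxidase that reduces lipid peroxides, was at 43.4 ± 14.7 CPM in DMSO and 74.2 ± 14.8 CPM in palbociclib, with a log2 fold change 0.78 (SE 0.26; adjusted p = 0.149). It did not pass, though it did without DMSO replicate 2 (0.0218) and with no filter on low counts (0.0352). Neither did SLC7A11, the cystine transporter (-0.63, adjusted p 0.148), ACSL4 (0.19, adjusted p 0.771), TFRC, the transferrin receptor (-0.71, adjusted p 0.189), MBOAT2 (-0.13, adjusted p 0.809) or AIFM2, which encodes the ferroptosis suppressor FSP1 (-0.81, adjusted p 0.0583, but 0.0353 with DESeq2, 0.0371 with no filter and 0.0462 without DMSO replicate 2).

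Of 24 p53 target genes 1 rose, TP53INP1 (1.21, adjusted p 0.0434), and 1 fell, FDXR (-0.94, adjusted p 0.0264). Of 19 senescence-associated secretory genes IL1B rose (1.08, adjusted p 0.0254) and MMP3 fell (-1.25, adjusted p 0.0398). None of TP53INP1, FDXR, IL1B and MMP3 passed without DMSO replicate 1 (in turn 0.138, 0.0603, 0.14 and 0.0729), pimasertib replicate 1 (0.101, 0.0595, 0.0689 and 0.0786) or pimasertib replicate 2 (0.1, 0.0592, 0.0649 and 0.0837), or from the 4 libraries of the comparison (0.0943, 0.0533, 0.0641 and 0.0703), nor TP53INP1 with the stricter filter (0.0573). Without palbociclib replicate 1, FDXR (0.143), IL1B (0.0523) and MMP3 (0.14) did not pass, nor TP53INP1 (0.197), FDXR (0.0809) and MMP3 (0.0727) without palbociclib replicate 2, nor MMP3 without DMSO replicate 2 (0.107). The p53 list as a whole lay lower (camera adjusted p 0.00673, adjusted p 0.655 with an estimated correlation), but not without DMSO replicate 2 (0.0702) or palbociclib replicate 1 (0.116). Of 19 ERK/MAPK output genes 1 passed, FOSL1 (-1.29, adjusted p 0.0174), which did not pass without DMSO replicate 1 (0.0636), palbociclib replicate 2 (0.0882), pimasertib replicate 1 (0.0556) or pimasertib replicate 2 (0.0543), or from the 4 libraries of the comparison (0.0519). Without palbociclib replicate 1, 1 of the 19 passed as higher. The list as a whole had a median of 0.05 and did not pass (adjusted p 0.947).

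In 14 lists no member passed in palbociclib by the edgeR test. They were the ferroptosis-promoting, NRF2, ATF4/amino acid, cholesterol synthesis, antigen presentation, lysosome, extracellular matrix, ribosome biogenesis, cytosolic ribosomal protein, mitochondrially encoded, RNA stress, epithelial, leukocyte and endothelial genes, 268 genes together. At an unadjusted p under 0.05 there were 40 of them, with DESeq2 8, with limma-voom 2 and with no filter 13 (15 with members below the filter). Summed over the lists, 2 passed without DMSO replicate 1, 10 without DMSO replicate 2 and 10 without palbociclib replicate 1, among them 3 and 4 matrix genes in the last 2 fits. Of these lists, 4 passed as sets, each with a median log2 shift below 0.5 in size. Of the other 10, the lysosome and antigen presentation lists passed without DMSO replicate 2 (1.42e-04 and 0.0217) or palbociclib replicate 1 (9.37e-04 and 0.0243). Extracellular matrix genes lay higher (median 0.41, 7 genes adjusted over the list alone, camera adjusted p 8.39e-04, adjusted p 0.814 with an estimated correlation), but not without DMSO replicate 1 (0.106) or palbociclib replicate 2 (0.185). Ribosome biogenesis genes lay lower (median -0.35, adjusted p 0.00225, adjusted p 0.816 with an estimated correlation), but not without DMSO replicate 1 (0.418) or palbociclib replicate 2 (0.397). Cytosolic ribosomal protein genes lay higher (median 0.23, adjusted p 0.00129, adjusted p 0.816 with an estimated correlation), but not without DMSO replicate 2 (0.183) or palbociclib replicate 1 (0.109). Cholesterol synthesis genes lay lower (median -0.16, adjusted p 0.048, adjusted p 0.85 with an estimated correlation), but with a stricter filter on low counts the adjusted p was 0.103, without palbociclib replicate 1 it was 0.531, and without DMSO replicate 2 the direction turned (adjusted p 0.898).

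Over all 14839 tested genes, 526 differed between palbociclib and DMSO at an adjusted p under 0.05. Of these, 164 were higher and 362 lower, and 132 and 329 changed at least 2-fold. The authors' deposited table calls 629 genes for this comparison, 183 higher and 446 lower, and 479 genes were called in both, all in the same direction. The count was 332 without pimasertib replicate 1 and 333 without pimasertib replicate 2, 350 from the 4 libraries of the comparison, 882 with DESeq2 and 1097 with no filter on low counts. The number higher was 59 without DMSO replicate 1, 66 and 69 without pimasertib replicates 1 and 2, and 315 without DMSO replicate 2. Of the 526 genes, 245 passed in all 6 fits that left out 1 library, 38 higher and 207 lower.

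**Figure D1:**
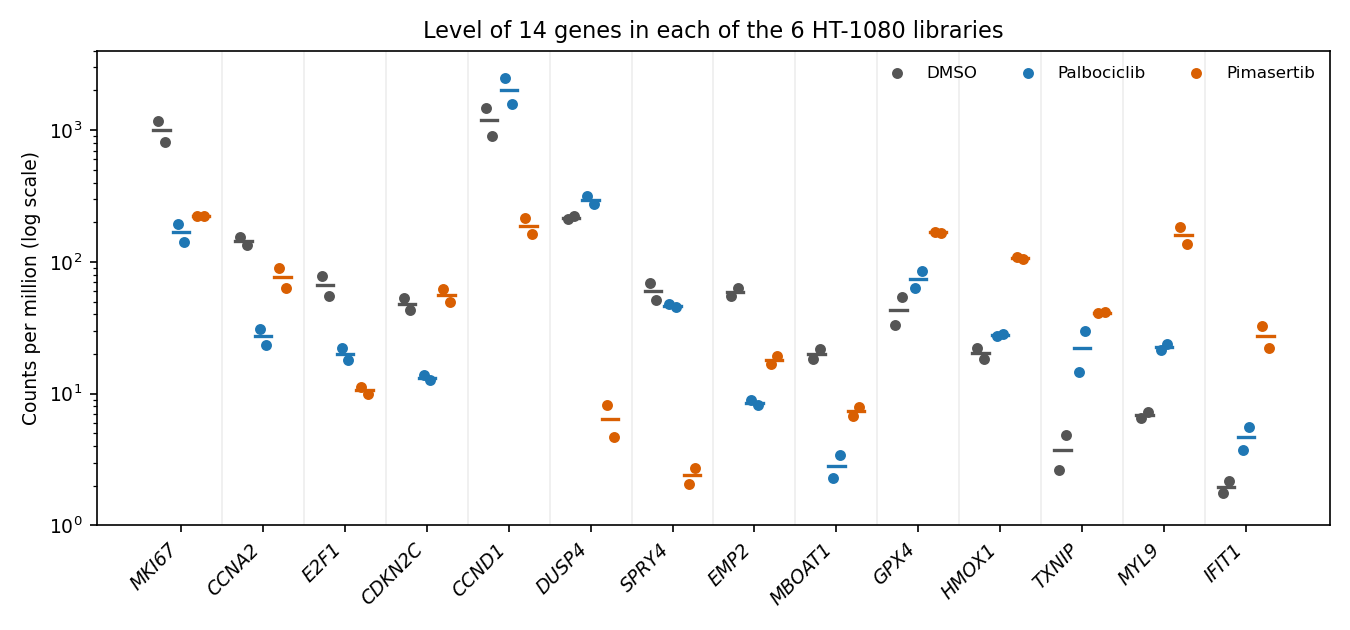
Level of 14 genes in CPM (log scale) in each of the 6 libraries, with points for single libraries and bars for the mean of each group of 2. MKI67 and CCNA2 lie lower with both drugs, CCND1, DUSP4 and SPRY4 are lowest in the pimasertib libraries, and GPX4 is highest there.

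The comparison of pimasertib with DMSO asked which genes changed when MEK was inhibited. Some target genes of ERK signalling were among those that fell. DUSP4, a phosphatase that acts on ERK (ENSG00000120875, chromosome 8, positions 29190581 to 29208185, minus strand), was at 217 ± 9.39 CPM in DMSO and 6.42 ± 2.49 CPM in pimasertib, 33.6-fold lower, with a log2 fold change -5.07 (SE 0.32; adjusted p = 1.04e-05). SPRY4, a feedback inhibitor of receptor signalling (ENSG00000187678, chromosome 5, positions 141689992 to 141706020, minus strand), went from 59.8 ± 12.5 to 2.4 ± 0.454 CPM (log2 fold change -4.64 (SE 0.27; adjusted p = 8.76e-06)). CCND1 (ENSG00000110092, chromosome 11, positions 69455855 to 69469242, plus strand) went from 1185 ± 402 to 188 ± 37.8 CPM (log2 fold change -2.65 (SE 0.34; adjusted p = 5.74e-04)).

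Of 19 tested ERK/MAPK output genes 14 fell, and 14 adjusted over the list alone, with a median log2 fold change of -2.17. All 14 calls held in each fit that left out 1 library. The camera adjusted p was 1.34e-13, or an adjusted p of 0.138 with an estimated correlation. The list included the transcription factors ETV4 (-4.76, adjusted p 1.04e-05) and ETV5 (-3.89, adjusted p 1.81e-05), which ERK induces, and FOSL1, an AP-1 subunit (-2.65, adjusted p 1.24e-04). DUSP6, an ERK phosphatase, was below the filter, with 0 and 7 counts in DMSO, 5 and 5 in palbociclib and 0 and 0 in pimasertib. Of the drug's targets, MAP2K1, which encodes MEK1, fell (-1.18, SE 0.22, adjusted p 0.00405), though not without pimasertib replicate 2 (0.06). MAP2K2, which encodes MEK2, did not pass (0.10, SE 0.24, adjusted p 0.801).

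The largest decreases by the fixed rule were those of ESM1 (-6.70, adjusted p 7.68e-06), an endothelial proteoglycan, PREX1 (-5.52), an exchange factor for Rac, the collagenase MMP1 (-5.39), ACOX2 (-5.31), a peroxisomal oxidase, DUSP4, IL8 (-4.99; current symbol CXCL8), EMP1 (-4.83) and ETV4. Of the 8 largest increases, the top was WISP2 (current symbol CCN5), with no count in DMSO and 16 ± 4.67 CPM in pimasertib, at least 164-fold higher against a floor of 3 counts over the DMSO group. It was followed by the cytokine IL32 (7.64, adjusted p 8.76e-06), the complement protease C1R (6.45, adjusted p 3.60e-05), EDIL3 (5.91) and MATN2 (5.79), both secreted matrix proteins. The other 3 were PDGFB (6.49, adjusted p 0.00104, but 0.0589 with DESeq2), CHI3L1 (7.34, adjusted p 9.91e-05, but 0.074 without DMSO replicate 1) and COL1A1 (6.06, adjusted p 0.00143, but 0.336 without DMSO replicate 1, 0.191 without DMSO replicate 2 and 0.169 with no filter on low counts).

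Of the 40 replication and G1/S genes 37 fell in pimasertib (39 adjusted over the list alone; median -1.55), with a camera adjusted p of 3.57e-22, or an adjusted p of 0.569 with an estimated correlation. E2F1 went from 66.5 ± 16.6 to 10.6 ± 0.902 CPM (log2 fold change -2.65 (SE 0.25; adjusted p = 9.88e-05)). Of the 36 G2/M genes 35 fell (36 adjusted over the list alone; median -1.21; adjusted p 7.78e-18, or adjusted p 0.569 with an estimated correlation), but 15 without pimasertib replicate 2. MKI67 was at 223 ± 1.94 CPM (log2 fold change -2.15 (SE 0.27; adjusted p = 5.38e-04)), and PLK1 (-1.70) and CDC20 (-1.75), which drives exit from mitosis, had adjusted p of 3.92e-04 and 4.66e-04. Of 15 cyclin D, RB and brake genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with 3 falling without pimasertib replicate 2. CCND1, CDKN2D (-2.14, adjusted p 0.00141), which encodes the CDK4/6 inhibitor p19, and RBL1 (-1.32, adjusted p 0.00269) held in each such fit. CDK2 (-1.24, adjusted p 0.00369) and CCNE2 (-1.73, adjusted p 0.00597) fell, but not without pimasertib replicate 2 (0.0531 and 0.0631). CDKN1B, which encodes the inhibitor p27, rose (0.86, adjusted p 0.0191), but not without DMSO replicate 1 (0.0577), pimasertib replicate 1 (0.101) or pimasertib replicate 2 (0.0773). CDK4 (-0.53, adjusted p 0.125), CDK6 (-0.02, adjusted p 0.97), RB1 (-0.43, adjusted p 0.208), CCNE1 (-0.57, adjusted p 0.153) and CDKN1A (0.53, adjusted p 0.109, but 0.0389 with DESeq2) did not pass.

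Genes of the contractile apparatus rose with pimasertib. MYL9 (ENSG00000101335, chromosome 20, positions 35169887 to 35178228, plus strand) was at 6.87 ± 0.52 CPM in DMSO and 161 ± 34.8 CPM in pimasertib, 23.4-fold higher (log2 fold change 4.55 (SE 0.25; adjusted p = 7.68e-06)). Of 17 contractile and SRF/YAP target genes 9 rose (10 higher and 1 lower adjusted over the list alone; median 1.18; camera adjusted p 4.92e-05, or adjusted p 0.394 with an estimated correlation). They included TAGLN (4.66, adjusted p 7.48e-05), TPM1 (3.28, adjusted p 3.32e-05) and CNN1, calponin of smooth muscle, with 1 count in DMSO and 155 in pimasertib (ratio 148, 95% counting interval 26.1 to 5867). Without either DMSO library or palbociclib replicate 1, 1 of the 17 fell. Interferon-stimulated genes rose too. Of 24, 15 were higher (16 adjusted over the list alone), the median was 1.61, also with BST2, which had no count in DMSO, set at its bound, and the adjusted p was 7.35e-09, or an adjusted p of 0.222 with an estimated correlation. IFIT1 (ENSG00000185745, chromosome 10, positions 91152303 to 91163745, plus strand) went from 1.96 ± 0.284 to 27.3 ± 7.26 CPM (log2 fold change 3.79 (SE 0.34; adjusted p = 7.87e-05)), and IFI27 (5.17, adjusted p 2.30e-04), IFI6 (3.45, adjusted p 0.00141) and RSAD2 (5.43, adjusted p 0.00235) also rose. Of 16 leukocyte markers, 12 were below 1 CPM in the pimasertib libraries, and none of the 4 tested passed.

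Genes of the lysosome, the extracellular matrix and antigen presentation were higher in pimasertib, and these are lists that also differed between replicate numbers. Of 21 extracellular matrix genes 12 rose (15 adjusted over the list alone; median 1.38, the same with BGN, without a count in DMSO, at its bound; camera adjusted p 3.63e-07, or adjusted p 0.748 with an estimated correlation), 7 without DMSO replicate 1 and 6 without pimasertib replicate 2. SPARC (2.77, adjusted p 0.00116), a collagen-binding protein, and FBN1 (2.53, adjusted p 1.08e-04), fibrillin of elastic fibres, were among those that held in each such fit. Of 27 lysosome genes 13 rose (16 adjusted over the list alone; median 1.02; adjusted p 1.41e-05, or adjusted p 0.754 with an estimated correlation), but 4, 5 and 3 without DMSO replicate 1, pimasertib replicate 1 and pimasertib replicate 2. GPNMB (3.72, adjusted p 0.00141) and the autophagy receptor SQSTM1 (1.78, adjusted p 5.74e-04) were among those that held throughout. Of 16 antigen presentation genes 9 rose (12 adjusted over the list alone; median 1.15; adjusted p 5.28e-05, or adjusted p 0.655 with an estimated correlation), and 3, 5 and 2 without those same libraries. NLRC5, a transactivator of class I genes (1.23, adjusted p 0.00375), and the immunoproteasome subunit PSMB9 (1.35, adjusted p 0.0031) held throughout. HLA-B and HLA-C were among the 9, but near-identical copies leave their counts uncertain, and neither passed without DMSO replicate 1 (adjusted p 0.245 and 0.2) or pimasertib replicate 2 (0.0875 and 0.149), nor HLA-B without DMSO replicate 2 (0.072). The median log2 difference of replicate 2 from replicate 1 was 0.91 in DMSO, 0.82 in palbociclib and 0.46 in pimasertib for lysosome genes, 0.70 in DMSO, 0.51 in palbociclib and 0.36 in pimasertib for matrix genes and 0.71 in DMSO, 0.55 in palbociclib and 0.42 in pimasertib for antigen presentation genes. Genes for proteins with a hydrophobic segment had a median log2 fold change of 0.17 in pimasertib and the others −0.13, against 0.0031 and −0.0062 in palbociclib.

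Genes of ribosome biogenesis and MYC targets fell in pimasertib, 14 of 25 (23 adjusted over the list alone; median -0.78; camera adjusted p 4.88e-08, or adjusted p 0.726 with an estimated correlation). The count was 6 without DMSO replicate 1, 4 without pimasertib replicate 1 and 1 without pimasertib replicate 2, and LYAR, a nucleolar protein (-1.81, adjusted p 5.81e-04), held throughout. These genes were also lower in replicate 2 than in replicate 1, with medians of -0.44 in DMSO, -0.38 in palbociclib and -0.20 in pimasertib. Of 19 senescence-associated secretory genes 7 fell and 3 rose (8 and 4 adjusted over the list alone), and the list did not pass as a set (adjusted p 0.0602), but did without DMSO replicate 1 (1.52e-04), palbociclib replicate 1 (0.0477) or 2 (0.0414) or pimasertib replicate 2 (0.0131), and with the stricter filter (0.0140). The senescence-associated genes were higher in replicate 2 than in replicate 1, with medians of 1.05 in DMSO, 0.77 in palbociclib and 0.46 in pimasertib. The interleukins IL1B (-4.48, adjusted p 8.76e-06) and IL8 and the protease MMP1 fell. Without pimasertib replicate 1, 4 of them fell. The number that rose was 1 without DMSO replicate 1, 5 without DMSO replicate 2 and 1 without pimasertib replicate 2.

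GPX4 rose with pimasertib. It (ENSG00000167468, chromosome 19, positions 1103936 to 1106787, plus strand) was at 43.4 ± 14.7 CPM in DMSO and 167 ± 3.68 CPM in pimasertib, 3.86-fold higher (log2 fold change 1.95 (SE 0.27; adjusted p = 8.48e-04)). Of the 24 ferroptosis-protective genes 3 rose and 2 fell, the same adjusted over the list alone, and the list did not pass as a set (adjusted p 0.764). Besides GPX4, the ferritin genes FTL (1.22, adjusted p 0.00683) and FTH1 (0.86, adjusted p 0.025) rose, though both have many processed pseudogenes and neither passed without pimasertib replicate 1 (0.0564 and 0.101), which left 1 gene that rose. FTH1 did not pass either without DMSO replicate 1 (0.109), DMSO replicate 2 (0.0566) or pimasertib replicate 2 (0.122). MBOAT1 (-1.46, adjusted p 0.00507) fell, but not without pimasertib replicate 1 (0.0554), and VKORC1L1, which reduces vitamin K (-0.69, adjusted p 0.0339), lost its call without either DMSO library (0.0645 and 0.0997) or either pimasertib library (0.174 and 0.0989) and with the 4 libraries of the comparison alone (0.0517). EMP2 fell from 59 ± 5.37 to 18.1 ± 1.73 CPM (log2 fold change -1.71 (SE 0.21; adjusted p = 4.11e-04)). SLC7A11 (0.37, adjusted p 0.234), ACSL4 (-0.61, adjusted p 0.127), AIFM2 (-0.39, adjusted p 0.192), MBOAT2 (0.15, adjusted p 0.637) and TFRC (-0.44, adjusted p 0.259) did not pass. Of 23 ferroptosis-promoting genes 1 rose, HMOX1, the heme oxygenase (2.40, adjusted p 7.08e-05). The number that rose was 3 without DMSO replicate 2, 4 and 4 without palbociclib replicates 1 and 2, 3 with DESeq2, 3 with limma-voom, 4 with no filter and 4 from the 4 libraries of the comparison.

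HMOX1 was also among the 5 of 21 NRF2 target genes that rose (5 adjusted over the list alone). There were 3 without DMSO replicate 1 and 2 without pimasertib replicate 1. The list's adjusted p of 0.045 (adjusted p 0.816 with an estimated correlation) was 0.248 without DMSO replicate 2, 0.0836 and 0.0861 without palbociclib replicates 1 and 2, and 0.209 without pimasertib replicate 1. Of 24 p53 targets 3 rose and 2 fell, the same adjusted over the list alone, and TP53INP1 (1.89, adjusted p 0.00133), TP53I3 (1.04, adjusted p 0.00387) and AEN (-1.23, adjusted p 0.00242) held in each fit that left out 1 library, in each of which 1 gene fell. Of 23 cholesterol synthesis genes 2 rose (HMGCS1 and LSS) and 2 fell (among them PMVK), and of 30 genes of fatty acid and phospholipid remodelling 2 rose and 4 fell. HMGCS1, LSS and PMVK did not pass without pimasertib replicate 1 (adjusted p 0.11, 0.11 and 0.0541) or pimasertib replicate 2 (0.0592, 0.113 and 0.124). Neither did HMGCS1, LSS and PMVK without DMSO replicate 1 (0.128, 0.158 and 0.0763), nor LSS without DMSO replicate 2 (0.0524). Without DMSO replicates 1 and 2 and pimasertib replicates 1 and 2, the number that fell was 1, 1, 0 and 0, and the number that rose 0, 6, 0 and 0. The cholesterol list did not pass as a set (adjusted p 0.335), but did without DMSO replicate 2 (0.0174). Of the fatty acid genes, 2 fell without DMSO replicate 2, 0 without pimasertib replicate 1 and 1 without pimasertib replicate 2, and 0, 1 and 0 rose without DMSO replicate 1, pimasertib replicate 1 and pimasertib replicate 2.

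Among 6 epithelial markers KRT8 rose (1.18, adjusted p 0.0154, but 0.133 without pimasertib replicate 1) and KRT18 fell (-1.03, adjusted p 0.00949, but 0.104 without pimasertib replicate 2), both with many near-identical pseudogenes. Among 5 endothelial markers ROBO4 fell (-2.56, adjusted p 8.38e-05) and EGFL7 rose (1.15, adjusted p 0.0463, but 0.202 without DMSO replicate 1, 0.104 and 0.255 without pimasertib replicates 1 and 2, and 0.0632 with a stricter filter on low counts). No leukocyte, mitochondrially encoded or cytosolic ribosomal protein gene passed by the edgeR test, of 63 genes, with 3 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma-voom, 2 with no filter and 1 from the 4 libraries of the comparison. The 4 tested leukocyte markers all had positive log2 fold changes (median 0.71, camera adjusted p 0.265). Mitochondrially encoded genes rose without DMSO replicate 2 (2), palbociclib replicate 1 (1) and palbociclib replicate 2 (1).

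Over all 14839 genes, 3376 differed between pimasertib and DMSO, 1644 higher and 1732 lower, and 1288 and 1047 of them changed at least 2-fold. The authors' deposited table calls 3445 genes, 1741 higher and 1704 lower, and 3085 genes were called in both, all in the same direction. The count was 1860 without DMSO replicate 1 (868 higher, 992 lower), 1564 without pimasertib replicate 1 (779 and 785) and 1103 without pimasertib replicate 2 (581 and 522). Of the 3376 genes, 919 passed in all 6 fits that left out 1 library, 476 higher and 443 lower.

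**Figure D2:**
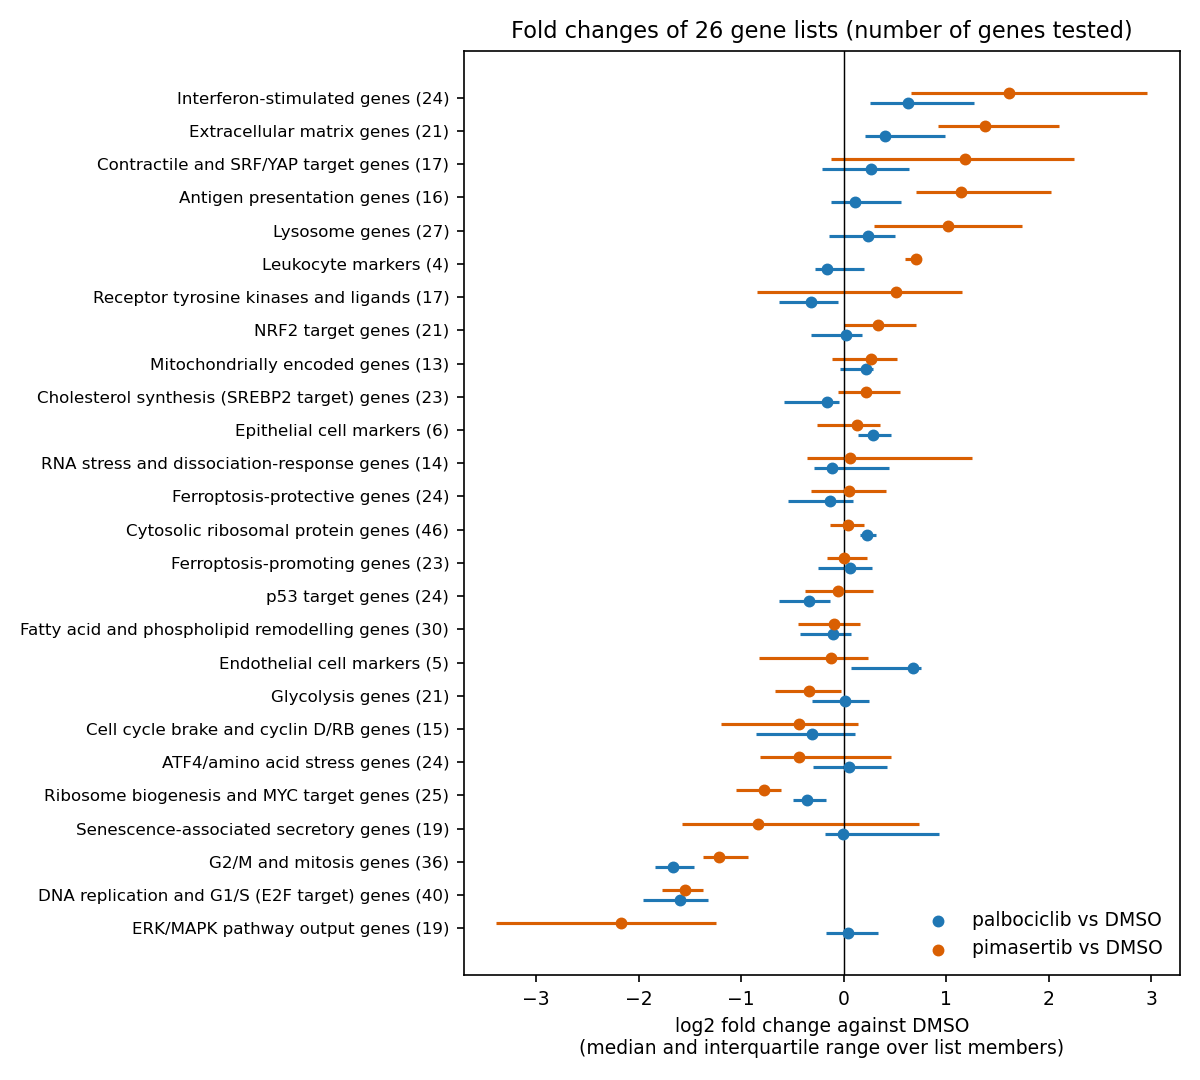
Median (point) and interquartile range (line) of the log2 fold change against DMSO over the tested members of 26 gene lists, for palbociclib and pimasertib, with the number of tested genes in brackets. The medians of the replication list are −1.60 and −1.55, while that of the ERK/MAPK list is 0.05 with palbociclib and −2.17 with pimasertib.

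The direct comparison of the drugs tested whether their effects differed. ERK/MAPK output genes were higher in palbociclib than in pimasertib, 13 of 19 (16 adjusted over the list alone; median 1.92; camera adjusted p 1.61e-20, or adjusted p 0.138 with an estimated correlation). CCND1 was at 2018 ± 642 CPM in palbociclib and 188 ± 37.8 CPM in pimasertib (log2 fold change 3.42 (SE 0.35; adjusted p = 2.52e-04)), and DUSP4 at 297 ± 28.7 and 6.42 ± 2.49 CPM (log2 fold change 5.52 (SE 0.32; adjusted p = 1.42e-05)). CDKN2C, at 48.3 ± 6.89 CPM in DMSO, was lower in palbociclib, at 13.2 ± 0.76 CPM, than in pimasertib, at 56.1 ± 8.74 CPM (log2 fold change -2.08 (SE 0.22; adjusted p = 2.82e-04)).

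By the fixed rule, the genes highest in palbociclib relative to pimasertib were GPR116, an adhesion receptor (current symbol ADGRF5), with 470 counts in palbociclib and 2 in pimasertib (ratio 245, 95% counting interval 67.4 to 2028), ESM1 (5.98, adjusted p 1.20e-05), MYEOV (5.81), IL1B (5.56, adjusted p 1.20e-05), DUSP4 and ACOX2 (5.42). The lowest were WISP2, with 3 counts in palbociclib and 518 in pimasertib (ratio of pimasertib to palbociclib 166, interval 56.4 to 806), CHI3L1 (-6.77, adjusted p 1.73e-04), C1R (-5.51), MATN2 (-4.96), TRAF1 (-4.92), an adaptor of TNF receptors, and PDGFB (-5.19, adjusted p 0.00293, but 0.0589 without pimasertib replicate 2 and 0.185 with DESeq2).

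The replication list did not differ as a set between the drugs (median -0.03, adjusted p 0.947), which does not show that it was equal. Of its 40 genes 1 passed, E2F1, higher in palbociclib (0.92, adjusted p 0.0392), which did not pass over the list alone, with limma-voom (0.0558) or without palbociclib replicate 1 (0.19), pimasertib replicate 1 (0.137) or pimasertib replicate 2 (0.258). In the other 3 such fits, without either DMSO library or palbociclib replicate 2, 1 gene of the list was lower. G2/M genes were lower in palbociclib, 7 of 36 (13 adjusted over the list alone; median -0.51; adjusted p 6.05e-05, or adjusted p 0.754 with an estimated correlation), but 3, 1 and 2 without palbociclib replicate 1, pimasertib replicate 1 and pimasertib replicate 2. KIF20A, a kinesin of cytokinesis (-1.18, adjusted p 0.00404), held in each such fit, and CCNA2 (-1.49, adjusted p 0.00386) in all but that without pimasertib replicate 1 (0.051). Of the 15 cyclin D, RB and brake genes 1 was higher and 3 lower in palbociclib (2 and 3 adjusted over the list alone). The lower ones besides CDKN2C were CDKN1B (-0.96, adjusted p 0.0221) and CDKN1A (-0.86, adjusted p 0.0362), and neither passed without palbociclib replicate 1 (0.199 and 0.29), pimasertib replicate 1 (0.13 and 0.177) or pimasertib replicate 2 (0.103 and 0.138), nor CDKN1A without palbociclib replicate 2 (0.0648).

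Interferon-stimulated genes were lower in palbociclib than in pimasertib, 9 of 24 (13 adjusted over the list alone; median −1.0; camera adjusted p 8.21e-06, or adjusted p 0.312 with an estimated correlation), and 5 without either pimasertib library. IFIT1 (-2.54, adjusted p 6.57e-04) and IFI27 (-3.30, adjusted p 0.00181) held throughout. Of 17 contractile genes 10 were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p 4.81e-05, or adjusted p 0.394 with an estimated correlation), with 4 lower without pimasertib replicate 1. MYL9 (-2.83, adjusted p 6.88e-05) was among the lower ones and TGFBI (1.84, adjusted p 9.98e-04) was the higher one. Of 21 matrix genes 8 were lower (9 lower and 1 higher adjusted over the list alone; adjusted p 2.77e-04, or adjusted p 0.782 with an estimated correlation), 4 without pimasertib replicate 1 and 3 without pimasertib replicate 2, and 2 were higher without palbociclib replicate 1. Of 27 lysosome genes 4 were lower (10 adjusted over the list alone; adjusted p 7.23e-06, or adjusted p 0.754 with an estimated correlation). That count ranged from 0 without palbociclib replicate 1, 0 without pimasertib replicate 2 and 1 without pimasertib replicate 1 to 10 and 11 without DMSO replicates 1 and 2 and 16 without palbociclib replicate 2. Of 16 antigen presentation genes 5 were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p 4.81e-05, or adjusted p 0.655 with an estimated correlation), with 2, 9, 3 and 2 lower without palbociclib replicates 1 and 2 and pimasertib replicates 1 and 2. The higher one, CIITA (1.63, adjusted p 0.0485), did not pass without palbociclib replicate 2 (0.107) or pimasertib replicate 1 (0.209), with DESeq2 size factors (0.0504) or with the stricter filter (0.0778). The median log2 difference between palbociclib and pimasertib was −0.18 for genes of proteins with a hydrophobic segment and 0.096 for the others. Ribosome biogenesis genes were higher in palbociclib as a set, with 2 of 25 past the threshold (3 adjusted over the list alone; median 0.51; adjusted p 3.23e-06, or adjusted p 0.754 with an estimated correlation) and 0, 0, 0 and 4 without palbociclib replicate 1, pimasertib replicate 1, pimasertib replicate 2 and DMSO replicate 2.

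Of the 24 ferroptosis-protective genes 4 were lower in palbociclib than in pimasertib (4 adjusted over the list alone), 1 without palbociclib replicate 1 and 0 without either pimasertib library. They were MBOAT1 (-1.35, adjusted p 0.0179), GPX4 (-1.17, adjusted p 0.0191), FTL (-1.15, adjusted p 0.0158) and SLC7A11 (-0.99, adjusted p 0.0153). Without pimasertib replicate 1 their adjusted p were 0.0712, 0.11, 0.114 and 0.114, and without pimasertib replicate 2 they were 0.143, 0.123, 0.0741 and 0.0597. Without palbociclib replicate 1, those of MBOAT1, GPX4 and FTL were 0.104, 0.102 and 0.0673, and without palbociclib replicate 2 those of FTL and SLC7A11 were 0.0852 and 0.0689. The list passed as a set (adjusted p 0.0213, or adjusted p 0.569 with an estimated correlation), but not without palbociclib replicate 2 (0.0741) or pimasertib replicate 1 (0.0953). EMP2 was lower in palbociclib as well (-1.08, adjusted p 0.0101), though not without pimasertib replicate 2 (0.0921). Of the 23 ferroptosis-promoting genes HMOX1 was lower in palbociclib (-1.94, adjusted p 2.57e-04). With no filter, from the 4 libraries of the comparison or without either DMSO library 4 were lower and 1 higher, with DESeq2 2 and 1, and without palbociclib replicate 2 3 were lower. Of 21 NRF2 targets 5 were lower (5 adjusted over the list alone), 2 without palbociclib replicate 2, 2 without pimasertib replicate 1 and 3 without pimasertib replicate 2. Their adjusted p as a set was 0.0148 (adjusted p 0.816 with an estimated correlation), 0.25 without palbociclib replicate 2 and 0.154 without pimasertib replicate 1.

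Cholesterol synthesis genes lay lower in palbociclib than in pimasertib (median -0.53, adjusted p 0.00366, or adjusted p 0.816 with an estimated correlation, and 0.0733 without palbociclib replicate 1), with 2 of 23 past the threshold and 0, 0 and 0 without palbociclib replicate 1, pimasertib replicate 1 and pimasertib replicate 2. Senescence-associated secretory genes lay higher as a set (adjusted p 0.0118, or adjusted p 0.816 with an estimated correlation), but not without palbociclib replicate 2 (0.18) or pimasertib replicate 1 (0.0953). Of 19, 7 were higher and 1 lower (7 and 2 adjusted over the list alone), with 4, 3 and 3 higher without palbociclib replicate 2, pimasertib replicate 1 and pimasertib replicate 2, and 4 lower without palbociclib replicate 2. Cytosolic ribosomal protein genes lay slightly higher as a set (median 0.18, adjusted p 0.0209, or adjusted p 0.816 with an estimated correlation), but not without palbociclib replicate 1 (0.116), without pimasertib replicate 2 (0.207) or with a stricter filter on low counts (0.0537). By the edgeR test none of its genes, the leukocyte markers or the mitochondrially encoded genes passed, of 63, with 6 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom, 1 with no filter, 1 from the 4 libraries of the comparison, and 1 without either DMSO library or palbociclib replicate 2. Of 24 p53 targets 3 were lower (5 adjusted over the list alone), and 1 without either pimasertib library. Of the 30 fatty acid and phospholipid genes MBOAT1 was the one past the threshold, with the limits given above, and without either DMSO library 2 were lower and 1 higher. Of the other cell type markers, KRT18 was higher in palbociclib (0.83, adjusted p 0.0439), though not without palbociclib replicate 1 (0.222), pimasertib replicate 1 (0.112) or pimasertib replicate 2 (0.314), and ROBO4 was higher (2.44, adjusted p 1.49e-04), the number of endothelial markers higher being 2 without either DMSO library.

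Over all 14839 genes, 1393 differed between the drugs, 640 higher and 753 lower in palbociclib, and 508 and 636 of them at least 2-fold. The count was 863 without palbociclib replicate 1, 538 without pimasertib replicate 1, 458 without pimasertib replicate 2 and 2256 with no filter on low counts. In these 3 leave-outs 445, 243 and 227 were higher and 418, 295 and 231 lower, and without palbociclib replicate 2 the lower ones were 1173. Of the 1393 genes, 375 passed in all 6 fits that left out 1 library, 188 higher and 187 lower in palbociclib.

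Both drugs lowered many of the same genes. Of the genes called against DMSO, 124 were higher and 305 lower with both drugs, where independent lists of the same sizes would share 18.2 and 42.3. MKI67, CCNA2, EMP2 and MBOAT1 were lower with both, although CCNA2 fell with pimasertib (-0.91, adjusted p 0.022) only in fits that kept DMSO replicate 1 (0.0709 without it) and pimasertib replicate 2 (0.184), and MBOAT1 only in those that kept pimasertib replicate 1 (0.0554). TXNIP (2.58 and 3.46), SESN3 (2.02 and 2.09) and MXD4 (1.97 and 1.99) were higher with both. The number shared was 263 without DMSO replicate 1, 236 without pimasertib replicate 1 and 179 without pimasertib replicate 2, in turn 39, 42 and 46 higher and 224, 194 and 133 lower. The number higher was also 271 without DMSO replicate 2, 189 without palbociclib replicate 1 and 77 without palbociclib replicate 2. A further 87 genes passed with palbociclib alone and 2937 with pimasertib alone, counts that by themselves do not show a difference between the drugs.

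In 10 genes both calls pointed in opposite directions. There were 2 such genes without DMSO replicate 1, 6 without palbociclib replicate 2, 2 without pimasertib replicate 1 and 4 without pimasertib replicate 2. GPR116 (1.48 with palbociclib, and 165 counts in DMSO against 2 in pimasertib), IL1B (1.08 and -4.48) and MYEOV (1.20 and -4.61) were higher with palbociclib and lower with pimasertib. Their palbociclib calls had adjusted p of 0.0175, 0.0254 and 0.0255, and without DMSO replicate 1 of 0.0738, 0.14 and 0.117. GPR116 and MYEOV also lost theirs without palbociclib replicate 2 (0.0871 and 0.0972), MYEOV without DMSO replicate 2 (0.0561) and pimasertib replicate 1 (0.0511), and IL1B without palbociclib replicate 1 (0.0523) and either pimasertib library (0.0689 and 0.0649). The direct comparisons of the drugs passed for all 3, as above. The other 7, INPP4B, POC1B, ATP1B1, ETS2, SULT1B1, MEX3B and GALNT4, fall outside the fixed rule and were named after their values were seen.

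Across the 14839 genes, which are not independent replicates, the log2 fold changes of the drugs had a Pearson correlation of 0.58. Both were taken against the same 2 DMSO libraries. In 50 simulations of unchanged groups all libraries, DMSO included, were drawn anew from the DMSO means, with both drug groups set against the same simulated DMSO libraries. They gave a mean of 0.50 (0.475 to 0.526) over the 13826 to 13908 of these genes that passed the filter in the simulated counts. The draws were independent between genes and held no shift between replicate numbers, so they lack variation that genes share in the measured libraries. The covariance was 0.553, against 0.0961 in the simulations, a difference of 0.457. The simulations gave at most 2 genes higher and 1 lower in both. With 2 DMSO libraries the controls could not be split into groups of 2, so part of the excess overlap may come from the shared controls. The correlation was 0.205 without palbociclib replicate 2 and 0.772 without DMSO replicate 2.

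**Figure D3:**
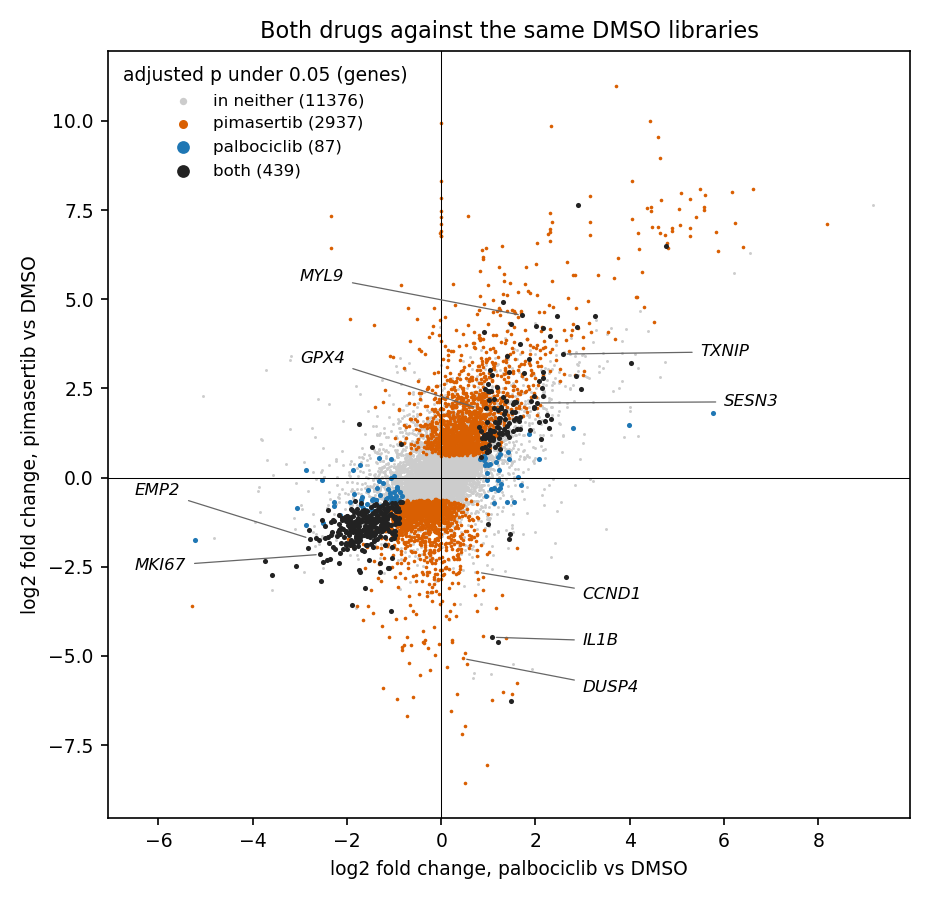
Log2 fold change of each of the 14839 tested genes against DMSO, with palbociclib on the horizontal and pimasertib on the vertical axis, coloured by which comparison had an adjusted p under 0.05. Black points (both) lie mostly in the lower left, where 305 genes fell with both drugs, and fitted values of genes without counts in a group depend on the prior count.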

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

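The alternative with 4 libraries and a replicate block was chosen after the data were seen, and all others before. Genes called against DMSO in palbociclib, main count 526, were 882 with the DESeq2 Wald test, 1097 with no filter on low counts and 350 from the 4 libraries of the comparison. For palbociclib against pimasertib, main count 1393, no filter gave 2256. The cause of these differences was not tested, except that leaving out the filter adds genes. Leaving out each library in turn gave 332 to 751 genes for palbociclib against DMSO, 1103 to 3897 for pimasertib against DMSO (main 3376), 458 to 1988 between the drugs, 179 to 634 for genes shared by both drugs in 1 direction (main 429), 29 to 39 of 78 list tests (main 36) and 185 to 290 calls of named genes (main 292). Counts that moved by more than 1.5 times were those without pimasertib replicates 1 and 2 (332 and 333 for palbociclib, 1564 and 1103 for pimasertib, 538 and 458 between the drugs, 236 and 179 shared, and 185 named calls without replicate 2), without DMSO replicate 1 (1860 for pimasertib, 263 shared) and without palbociclib replicate 1 (863 between the drugs). These fits leave an arm with 1 library, which is assumed to vary like the other groups. In no fit that left out a library did a call of the main fit change direction. A call lost in such a fit thus does not by itself show an effect that rests on the library left out. With an estimated correlation, a variant that also has few degrees of freedom, 0 list tests passed. With fry 13 passed, a test that asks whether a list's genes move one way and not whether they differ from other genes. The cholesterol synthesis list in palbociclib against DMSO turned its direction without DMSO replicate 2, with an adjusted p of 0.898 against 0.048, and over the libraries left out its adjusted p ranged from 3.08e-06 (without DMSO replicate 1) to 0.898. DESeq2 size factors, limma-voom, the stricter filter, protein-coding genes alone and the size threshold kept all these counts within 1.5 times where they were run, and DESeq2 size factors changed no list call. The median log2 fold change of all genes moved by at most 0.025 with DESeq2 size factors. The share of higher calls in palbociclib, 31.2%, was 40.2% with DESeq2, 47.2% with no filter and 20.6% from 4 libraries, and over the libraries left out it ran from 16.03% (without DMSO replicate 1) to 42.4% (without palbociclib replicate 1). An alternative pseudocount, planned for normalized values, does not apply to a test of counts. Lists whose median, mean and test differed in sign, none past the threshold, were the ferroptosis-promoting, NRF2, senescence-associated, leukocyte and RNA stress lists in palbociclib against DMSO, and the replication, mitochondrially encoded and RNA stress lists between the drugs.

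The replicate numbers were also fitted as a block. Across genes, deviations of same-numbered libraries from their group means correlated at 0.397 (DMSO and palbociclib), 0.351 (DMSO and pimasertib) and 0.345 (palbociclib and pimasertib), but with 2 numbers and no statement in the labels the libraries share only a number. With the replicate block the counts were 2953 for palbociclib, 6551 for pimasertib, 4702 between the drugs and 2074 for the genes shared by both drugs, and the share of higher calls in palbociclib was 43.4%. With the block and the 4 libraries of a comparison they were 4586, 6091 and 4578. With the block 39 of 78 list tests and 393 calls of named genes passed. Of the calls of the main fit, 525 of 526, 3374 of 3376 and 1392 of 1393 also passed with it, and COL1A1, in pimasertib against DMSO and between the drugs, was the named gene that did not. Named calls gained were 53, 13 and 37, among them GPX4, AIFM2, SLC7A11, TFRC and CCND1 in palbociclib against DMSO. In the lists without a call, 71 members passed with the block in palbociclib against DMSO, 16 in pimasertib against DMSO and 15 between the drugs.

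In data simulated at these depths, the edgeR test found 2.99% and 1.49% of 1.5-fold changes in palbociclib and pimasertib. It found 16.4% and 21.2% of 2-fold changes, and 73.4% and 87.1% of 4-fold changes. Genes that did not pass may therefore still have changed 2-fold, and some of them 4-fold. Fewer genes were changed per drug in the simulation than were called here with either drug, which makes the adjusted threshold stricter there. The simulated shares may thus be lower than the recovery in these comparisons.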

Other observations

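Some of the tests below were chosen only after the result was seen. They were those of RNA bound to the endoplasmic reticulum, of a culture state and of the replicate numbers for GPX4. The first of them followed a planned test of nuclear RNA, which met its bound for exclusion but was then read as open.

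Receptor tyrosine kinases and their ligands moved both ways in pimasertib. Of 17 tested genes, 7 rose and 5 fell against DMSO (8 and 5 adjusted over the list alone), and the list as a set did not pass (adjusted p 0.442). PDGFRB, the PDGF receptor beta, went from 4.13 ± 2.67 to 52.8 ± 4.44 CPM (log2 fold change 3.68 (SE 0.39; adjusted p = 1.96e-04)), and KIT (2.45, adjusted p 0.0011) and ROR1 (2.29, adjusted p 2.83e-04) also rose, while EGFR, the EGF receptor, fell from 287 ± 29 to 83.6 ± 15.7 CPM (log2 fold change -1.78 (SE 0.23; adjusted p = 5.90e-04)). These 4 held in each fit that left out 1 library, but 3, 4 and 3 genes rose and 3, 2 and 1 fell without DMSO replicate 1, pimasertib replicate 1 and pimasertib replicate 2. In palbociclib NRG1, a ligand of ERBB receptors, fell (-1.07, adjusted p 0.0166, but 0.0815 and 0.0544 without palbociclib replicates 1 and 2). The list lay lower (adjusted p 0.025, adjusted p 0.655 with an estimated correlation), though not without DMSO replicate 2 (0.215) or palbociclib replicate 2 (0.144) or with a stricter filter on low counts (0.0668). Between the drugs, 6 genes were lower in palbociclib, among them PDGFRB (-3.59, adjusted p 2.93e-04), KIT (-3.64, adjusted p 2.92e-04) and NRG1 (-1.59, adjusted p 8.83e-04), and 2 were higher, with 1, 0 and 1 without palbociclib replicate 1, pimasertib replicate 1 and pimasertib replicate 2. That set test gave an adjusted p of 0.0232 (adjusted p 0.655 with an estimated correlation), and 0.0643 without palbociclib replicate 2.

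Genes of the ATF4 and amino acid stress list also moved both ways in pimasertib. Of 24 ATF4 and amino acid stress genes 4 rose and 8 fell (4 and 11 adjusted over the list alone), the set did not pass (adjusted p 0.343), and in palbociclib against DMSO no gene of this list or of the RNA stress list passed with edgeR (6 and 5 at an unadjusted p under 0.05, 2 and 0 with DESeq2, 0 and 0 with limma-voom, and 2 and 0 without DMSO replicate 2 and 2 and 3 without palbociclib replicate 1). CTH, an enzyme of cysteine synthesis (3.08, adjusted p 0.0027), STC2 (2.33, adjusted p 0.00173) and ATF3 (1.98, adjusted p 0.00499) rose, and the leucine transporter SLC7A5 (-2.40, adjusted p 1.27e-04) and VLDLR (-1.75, adjusted p 0.00198) fell. The number that fell was 4, 4 and 2 without DMSO replicate 1, pimasertib replicate 1 and pimasertib replicate 2. Between the drugs 5 were higher and 4 lower in palbociclib (11 and 4 adjusted over the list alone). The camera adjusted p of the set was 0.0488, or adjusted p 0.754 with an estimated correlation and 0.0579 with the stricter filter on low counts. The set did not pass either without DMSO replicate 1, DMSO replicate 2, palbociclib replicate 1 or pimasertib replicate 2. Without DMSO replicates 1 and 2, palbociclib replicates 1 and 2 and pimasertib replicates 1 and 2, the higher ones were 10, 10, 2, 8, 2 and 1 and the lower ones 4, 4, 2, 3, 1 and 1. Of 14 RNA stress genes, which did not pass as a set (adjusted p 0.804), ATF3, JUNB (1.84, adjusted p 4.63e-04) and JUND (1.39, adjusted p 0.00116) rose, and JUN (-0.76, adjusted p 0.0294) and HSP90AA1 (-1.32, adjusted p 0.00961) fell, but not without pimasertib replicate 2 (0.181 and 0.111), nor JUN without DMSO replicate 1 (0.124) or pimasertib replicate 1 (0.105). ATF3 was lower in palbociclib than in pimasertib (-3.39, adjusted p 6.55e-04), as were JUNB (-1.22, adjusted p 0.00664) and JUND (-0.99, adjusted p 0.0118), the last 2 not without pimasertib replicate 1 (0.0575 and 0.0768) or 2 (0.06 and 0.0746), nor JUND without palbociclib replicate 1 (0.0867). Of 21 glycolysis genes 3 rose and 4 fell in pimasertib (set adjusted p 0.256), 1 and 1 without pimasertib replicate 1, 0 and 0 without pimasertib replicate 2, with 2 falling without DMSO replicate 2. SLC2A1, the glucose transporter GLUT1, was lower in palbociclib than in pimasertib (log2 fold change -2.26 (SE 0.30; adjusted p = 0.00112)). In palbociclib against DMSO 1 glycolysis gene passed, ALDOC (2.16, adjusted p 0.0475), but not without DMSO replicate 1 (0.15), palbociclib replicate 2 (0.108), pimasertib replicate 1 (0.111) or pimasertib replicate 2 (0.106), nor with limma-voom (0.058), the stricter filter (0.0557) or the 4 libraries of the comparison (0.109).

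Many genes shifted together between replicate 1 and replicate 2, with 3874 higher and 4111 lower in replicate 2 of all 3 groups (53.8% of those tested). GC content and gene length are argued against as the whole cause, since the lowest correlation between groups was 0.336 after each library's GC trend was removed (0.341 before) and 0.341 after the length trend was removed (0.345 before). More nuclear RNA in replicate 2, planned before its values were seen, was to be excluded by a median under 0.1 in any group. The medians of 10 tested RNAs listed as nuclear-retained were −0.020 in DMSO, 0.34 in palbociclib and 0.36 in pimasertib. The DMSO median thus met that bound. The explanation is left open because members in DMSO went both ways (quartiles −0.18 and 0.25), a reading adopted after the values were seen. Whether each listed RNA is nuclear in HT-1080 cells was not checked. Better recovery of RNA bound to the endoplasmic reticulum, tested after that, may account for part, as genes with a hydrophobic segment lay higher than the others by 0.262 or more in each group, though with the medians of both classes removed the lowest correlation was still 0.325 (0.364 before). A culture state that resembles the drug response may contribute. The DMSO replicate difference correlated at 0.274 with pimasertib minus palbociclib, and the palbociclib one at 0.322 with pimasertib minus DMSO. Within genes without a segment these were 0.254 and 0.315. The pimasertib replicate difference, however, correlated at −0.028 with palbociclib minus DMSO. Cholesterol synthesis genes were also higher in replicate 2, by medians of 0.63 in DMSO, 0.34 in palbociclib and 0.32 in pimasertib. The nuclear RNA, endoplasmic reticulum and culture state explanations stay open for 6 lists. They are the lysosome, matrix, antigen presentation, ribosome biogenesis, senescence-associated secretory and cholesterol synthesis lists.

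GPX4 was higher in the pimasertib libraries. GC content and gene length are argued against, since the 200 genes nearest in both had a median log2 fold change of 0.279 (95% interval 0.110 to 0.421), 0.143 of that of GPX4. The difference between replicate numbers was checked after the result was seen. GPX4 was higher by 2.36 and 1.61 within replicate numbers 1 and 2. The smaller of these exceeded the largest difference between replicate numbers (0.702) by 0.910. Each group had 1 library of each number, so a shift shared by the groups cancels between them, and this check adds no evidence on the cause. An effect of pimasertib on GPX4 remains as a hypothesis, found and tested on the same libraries. Whether it is specific to GPX4 among genes of its kind was not tested.

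Interferon-stimulated genes were higher in the pimasertib libraries. RNA from leukocytes is argued against, since the median level of 16 leukocyte markers in pimasertib, 0.0900 CPM, was 0.00952 of the median gain of 9.45 CPM of the 24 interferon-stimulated genes. The abundant marker LCP1, at 323 CPM in pimasertib and 258 CPM in DMSO, was high in the vehicle libraries as well. The 4 markers above the filter, LCP1 among them, all had positive log2 fold changes and none passed. An effect of pimasertib remains as a hypothesis, and no other technical explanation was tested for it.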
